A study of Rattus norvegicus with 47 samples.

How the data were processed

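Testis RNA of 47 rats, aged 90 days per the labels, was hybridised on 47 arrays with a universal rat reference RNA in the other dye. The treated animals had received 650 mg/kg of MAA. Each array file holds 22573 spots with 2 raw channels, 2 processed channels, a ratio and 2 flag columns. The raw columns are spot intensities up to 65535 per the file headers, without a background column. The processed columns are intensities that the authors normalized, with a shift per probe that was constant for all arrays of a hybridisation date on 11 of 12 dates. The ratio column is a log2 ratio of Cy3 over Cy5 that the authors normalized within each array by intensity. The scanner, the extraction software settings and the normalization method are not given in the sources used here. The authors left 2073 spots without processed values on every array, and these were tested apart from the rest, with 0 calls at each time and 103, 72, 116 and 160 spots at an unadjusted p under 0.05 at 4, 8, 12 and 24 h.

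The deposited series table holds log2 ratios too, and was not used for the results. In it 39 of 47 columns equal the ratio column of another array, 7 equal their own and 1 equals none, within a tolerance of 1e-06. Only 10 columns come from an array of the hybridisation date in their labels, and the columns are in order of date when named by the array they match. Each array file was therefore taken as labelled, and with the table as labelled 0 probes passed in each comparison. A wrong name on a single array file is not excluded. The file of MAA_12h animal 27 holds the Cy5 intensities and the flag column of another array, MAA_8h animal 15. Its M, which divides by that copied channel, was kept in the fit, and without it 541 probes passed at 12 h. The series table column of this array keeps its date's shift against the processed channels (SD over probes 1.5e-07). The ratio in the array's file does not (SD 0.28), and the deposited ratio was used as it stands in the file. The labels name Cy5 as testis, but the files show testis RNA in the channel headed Cy3. Genes typical of other organs, a set written after the files were seen, are bright in the other channel. The background flag is a limit on Cy3 on 47 of 47 arrays. With the testis channel alone 75 of 75 named calls had the same sign as reported, with the channel headed Cy5 alone 28 of 75, and with the series table as labelled 26 of 75.

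The raw intensities were normalized by loess within each array, with no background correction and no step between arrays, to M = log2(testis/reference). A background correction had been foreseen where background intensities are deposited, and none are. The correlation of M with the deposited ratio was 0.984 on the lowest array and 0.992 on the median array. A probe counts as above background where the background flag says so, and as saturated at 65535. The median array had a testis channel of 803 units and 60.8% of probes above background, and between 7 and 175 probes per array were saturated in the testis channel. Gene symbols came from the platform's annotation and a reference table of rat genes. They gave 12736 probes 1 symbol, 5 several and 7759 none, and 2262 genes have several probes.

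Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 47 arrays, with the 8 groups and the 12 hybridisation dates as fixed terms, 28 residual degrees of freedom and 6.75 prior ones. On 8 dates both treated and saline animals were hybridised, on 2 only treated and on 2 only saline ones. The contrasts were MAA minus saline at each time, an F test of the differences of this effect between times with the pairwise differences, and an F test between the saline groups. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 20500 probes of a contrast, and all p-values of genes and lists are from limma and two-sided. Animal numbers do not recur between groups, so no animal was measured more than once. Gene lists, 31 in number, were written before the data were examined. They were tested with camera at a preset correlation of 0.01 on 1 probe per gene, the one brightest in the testis channel on average, adjusted over 124 tests, with fry and an estimated correlation beside it. A list's count adjusted over the list alone corrects over its own members.

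The genes named follow a rule set before the data were examined. At each time these are the 6 genes with the largest rise and the 6 with the largest fall among called probes with 1 symbol. For each list up to 3 members with the smallest adjusted p over the 4 times are named at that time, called or not, and for the F tests the 5 genes with the smallest p. This gave 112 genes and 115 entries, of which 75 were called. Other called list members and unnamed probes are given by their number or value. No fold is given where neither group, or no saline array, was above background, except a bound against the background level.

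On simulated data of 20500 probes with 100 changed probes of each size, a log2 change of 1 was found in 83%, 87%, 85% and 93% of cases at 4, 8, 12 and 24 h. A change of 0.5 was found in 26%, 27%, 13% and 33%, with 0 wrong signs. Probes left unchanged made up 6, 11, 7 and 11 of the 115, 125, 105 and 137 calls. The simulated noise was independent between probes and was added to normalized values, without a scaling step or outlying arrays. These rates hold for such data and need not hold for the real arrays. The alternatives planned were: no date term, date as a random term, median centring, the channel headed Cy5 alone, the series table as labelled, a detection filter, array weights, a trended robust fit, an adjusted p under 0.01, a 1.5-fold minimum, 2 groups at a time, genes in place of probes, single dates, and leaving out each array. Chosen after the data were seen were normexp, the testis channel alone, the deposited ratio and processed channels, leaving out spots with image flag 3 or saturation, leaving out MAA_4h animal 3 and MAA_24h animal 44 together, and the position of each array between saline and MAA. That position is the projection of an array on the mean difference between treated and saline arrays of 12 or 24 h over the called probes, compared by exact permutation tests. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.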

Results

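RNA from the whole testis of 47 sexually mature male Sprague-Dawley rats was measured on Agilent oligonucleotide arrays, each testis sample against the same universal rat reference RNA in the other dye. The animals received methoxyacetic acid (MAA) or saline by intraperitoneal injection and were killed 4, 8, 12 or 24 h later. MAA is the active metabolite of the solvent ethylene glycol monomethyl ether and is known to kill spermatocytes. There were 6 animals in each of 8 groups, except for the saline group of 4 h with 5. Each array gave values for 20500 probes, of which 12736 carry the symbol of 1 gene here, for 9645 genes in all. The median brightness of the testis channel lay between 431 and 1749 units over the arrays, and 43.5% to 97.2% of the probes of an array stood above its background level. The number of arrays limits the precision, and the median standard error of a log2 change was 0.182, 0.176, 0.186 and 0.174 at 4, 8, 12 and 24 h.

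All signed values are log2 changes of the testis over reference ratio, MAA minus saline, with the channel headed Cy3 taken as testis. This opposes the dyes in the sample labels, which name Cy5 for testis, and with the labels' dyes every sign below would turn. The choice rests on the arrays. With the median log2(Cy3/Cy5) of each array set to 0, the 16 spermatocyte markers had a median of 1.06. Their median was above 0 on 47 of 47 arrays, although Mlh3 (-0.13) and Msh5 (-0.25) went the other way. In contrast, 16 genes typical of lung, kidney, brain and heart had a median of -3.88, above 0 on 0 of 47 arrays. This organ set was written after the files were seen, the spermatocyte list before. The array files were taken as labelled, although 39 of 47 columns of the series table hold the ratios of another array than the one named. With the names in the files 518 and 612 probes passed at 12 and 24 h, against at most 14 and 3 in other splits of the same arrays, and 0 did with the names in the series table, so the names in the files were used. A wrong name on a single array is not excluded by this.

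At 4 h the question was which transcripts respond first. Rbm38 (Gene ID 366262), which encodes an RNA-binding protein and is a known p53 target, was 1.74-fold higher after MAA (log2 change 0.80 ± 0.12 SE, 6 treated and 5 saline animals, adjusted p 0.00081). Dpf1 (Gene ID 50545), a subunit of a chromatin-remodelling complex, was 1.65-fold higher (0.73 ± 0.13 SE, adjusted p 0.0175), and passed in 42 of the 47 fits that leave out 1 array. Rbm38 stood at -0.49 ± 0.26 (SD) in saline animals and at 0.30 ± 0.084 (SD) in treated ones. The other 2 called probes, 5512 and 4919, have no gene symbol here and rose by 0.95 and 0.79. They are named because the list is so short, after their values were seen.

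With limma, 4 of 20500 probes passed at 4 h, 4 higher and 0 lower, and 1515 had an unadjusted p under 0.05. Within the 2 hybridisation dates that hold both groups, with 2 and 2 animals each, 0 probes passed, and across all probes the changes of the 2 dates correlated with r = 0.0715. No gene list passed at 4 h by limma's camera, over medians from -0.15 for the elongating spermatid markers to 0.14 for the blood cell markers, with a smallest adjusted p of 0.0681. Lcn5, an epididymal marker, was at 0.31 ± 0.20 (adjusted p 0.775). MAA_4h animal 3 stood apart from its group, and without it 5 probes passed.

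At 8 h Dpf1 was again higher, 1.72-fold (log2 change 0.78 ± 0.13 SE, 6 and 6 animals, adjusted p 0.0053). Its level was -0.51 ± 0.17 (SD) in saline and 0.29 ± 0.22 (SD) in treated animals. The unnamed probe 5512 was 1.96-fold higher (adjusted p 0.0002), and it passed at all 4 times, with 0.95, 0.97, 0.78 and 0.44. Dpf1 stood at 0.57 at 12 h, where it passed (adjusted p 0.015), and at 0.13 at 24 h, where it did not (adjusted p 0.731). Rbm38 did not pass after 4 h, with 0.39, 0.42 and 0.26 at 8, 12 and 24 h.

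Several genes that fell at 12 h were already lower at 8 h without passing. Cklf was at -0.76 ± 0.17 (adjusted p 0.178), Cks2 at -0.63 ± 0.21 (adjusted p 0.429) and Pou5f2 at -0.44. Of the 346 probes that rose at 12 h, 312 were above 0 at 8 h, with a median of 0.19, and of the 172 that fell at 12 h, 159 were below 0, with a median of -0.22, where 52.3% of all probes were above 0 at 8 h. Across all probes the changes of 8 and 12 h correlated with r = 0.297, and the shared dates alone give estimates a correlation of 0.151. Each array was then placed on an axis that runs from 0 at the saline mean to 1 at the treated mean of the 12 h animals, over the probes called at 12 h. This measure was added after the data were seen, and the calls and means left out the array being placed. The treated 8 h animals lay at 0.488 ± 0.0696 (SD, n = 6) and the saline 8 h animals at 0.133 ± 0.0672 (SD, n = 6). All 6 treated animals lay above all 6 saline animals (exact permutation test, two-sided p 0.0022, adjusted p 0.0043 over 4 tests with this measure). That is the smallest p the 924 splits can give, and the separation therefore held on each shared date. The splits moved arrays freely between hybridisation dates, some of which hold only treated or only saline animals. The exact p-values here therefore take no account of date. On the axis of the 24 h animals the means were 0.388 and 0.114, with the same exact p. The other 2 tests, at 4 h, did not pass (means 0.335 and 0.126, adjusted p 0.0577 on the 12 h axis, adjusted p 0.346 on the 24 h axis). Without animal 3 the treated 4 h mean was 0.219 on the 12 h axis (saline 0.126) and 0.137 on the 24 h axis (saline 0.109). The difference fell from 0.208 to 0.0926 on the 12 h axis (exact p 0.0397, unadjusted) and from 0.147 to 0.0282 on the 24 h axis (exact p 0.452). With the testis channel alone the adjusted p was 0.0144 and 0.0455 at 4 h and 0.0043 on both axes at 8 h. In that channel, without animal 3, all 5 treated 4 h animals lay above all 5 saline ones on the 12 h axis (difference 0.146, exact p 0.0079, unadjusted, the smallest that the 252 splits can give), with an exact p of 0.0317 on the 24 h axis.

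With limma, 2 of 20500 probes passed at 8 h, 2 higher and 0 lower, and 1459 had an unadjusted p under 0.05. Within the 2 shared dates, with 2 and 2 animals each, 1 and 0 probes passed (r = 0.0637 between the dates across all probes). No gene list passed, over medians from -0.12 for the calcium handling genes to 0.20 for the blood cell markers, with a smallest adjusted p of 0.117. Dbp, an output gene of the circadian clock, was at -0.45 ± 0.15 (adjusted p 0.421). Without MAA_4h animal 3, which shares the estimate of the spread and of the dates, 9 probes passed at 8 h, 6 higher and 3 lower. The count was 8 without MAA_8h animal 15 and 7 without MAA_12h animal 35, 6 without saline_4h animal 6, 5 without saline_8h animal 18, and 4 without each of MAA_8h animal 23, MAA_24h animals 39 and 43 and saline_24h animal 42.

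**Figure D1:**
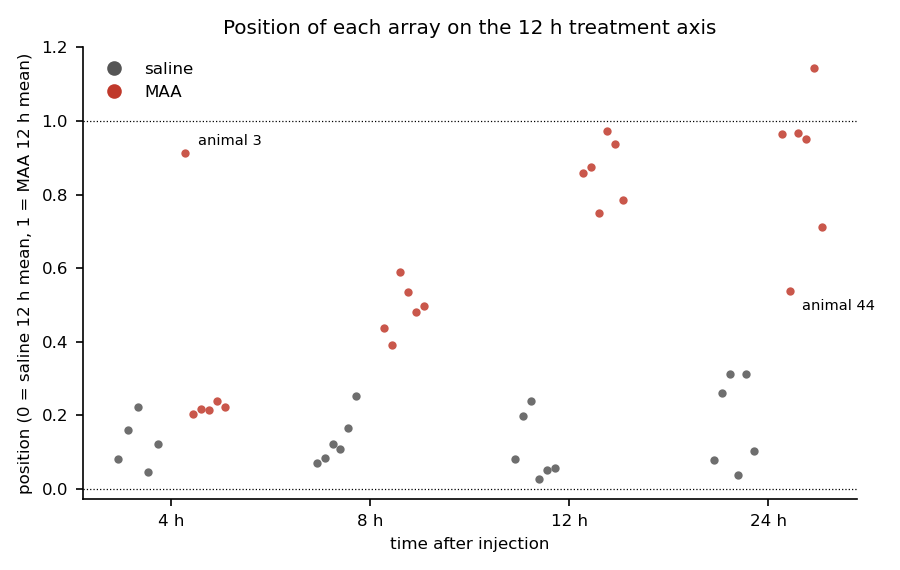
Position of each array between saline (0) and MAA (1) on the axis of the 12 h animals, without unit, by group and time. Each point is 1 animal: the treated 8 h animals lie from 0.391 to 0.588, MAA_4h animal 3 at 0.913 and MAA_24h animal 44 at 0.538.

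At 12 h many transcripts changed. Among probes with 1 gene symbol, the deepest falls were in Cklf (Gene ID 245978), a chemokine-like factor, 2.99-fold lower (log2 change -1.58 ± 0.18 SE, 6 and 6 animals, adjusted p 8.9e-06), and in Cks2 (Gene ID 498709), a cyclin-dependent kinase subunit needed for meiosis, 2.84-fold lower (-1.50 ± 0.22 SE, adjusted p 0.00016). The germ cell-less homologue Gmcl1 (Gene ID 312516) was 2.82-fold lower, though not past the threshold without MAA_12h animal 36, and Pou5f2 (Gene ID 680620), a POU-domain factor of male germ cells, 2.41-fold lower. Fstl1 (Gene ID 79210), which encodes a secreted glycoprotein, was at least 1.33-fold higher (adjusted p 0.00016), a bound, as no saline array showed it above background. S100a10 (Gene ID 81778), the partner of annexin A2, was 2.32-fold higher (1.21 ± 0.19 SE, adjusted p 0.00027).

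Cklf went from 0.85 ± 0.13 (SD) in saline animals to -0.68 ± 0.35 (SD) in treated ones, and its change was -1.74 on the date with 2 animals of each group and -1.52 on that with 2 saline animals and 1 treated one, animal 36. Klhdc1 and Thoc7, a component of the mRNA export machinery, were 2.37-fold (log2 change -1.25, but -0.77 with the testis channel alone) and 2.36-fold lower. Among the rises, the linker histone gene H1f4 was 2.14-fold higher (1.10, but 0.54 with the testis channel alone, where it did not pass, as without saline_12h animal 29), the sialyltransferase gene St3gal4 2.07-fold, and the actin-binding Cotl1 and the glutathione transferase gene Gstp1 2.05-fold each. Maoa, the monoamine oxidase, was 1.94-fold higher (0.95 ± 0.13 SE, adjusted p 3.6e-05). Among the 6 genes with the deepest falls, log2 changes ran from -1.58 to -1.24, and those of S100a10, H1f4, St3gal4, Cotl1 and Gstp1 from 1.03 to 1.21.

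With limma, 518 of 20500 probes passed at 12 h, 346 higher (66.8%) and 172 lower, for 331 genes, 248 higher and 83 lower. A gene counts here by 1 probe. Of 91 called genes with several probes, 57 had all other probes on the same side. Another probe was called the same way in 8 of the 91 and the opposite way in 0. Of the 518, 274 changed at least 1.5-fold, and 158 have no gene symbol here. On the date with 2 animals of each group 18 probes passed on their own, and on that with 2 saline animals and 1 treated one (animal 36) 6 did, with r = 0.133 between the dates across all probes. The share of rises depends on how the arrays are scaled: median centring in place of loess gave 28 higher and 125 lower, the testis channel alone 224 higher and 237 lower, the deposited ratio 128 higher and 266 lower and the processed channels 129 and 233. Of the 346 rises, 342 kept their sign with both median centring and the testis channel alone, and 171 of the 172 falls did, while 28 and 158 of the rises and 113 and 125 of the falls also passed in these 2. Without single animals the count fell to 226 (MAA_12h animal 36), 286 (MAA_12h animal 31), 282, 299, 329 and 334 (saline_12h animals 29, 26, 25 and 30), and the most, 614, came without MAA_4h animal 3. Without MAA_12h animal 27, whose reference channel is a copy of another array's, 541 probes passed.

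**Figure D2:**
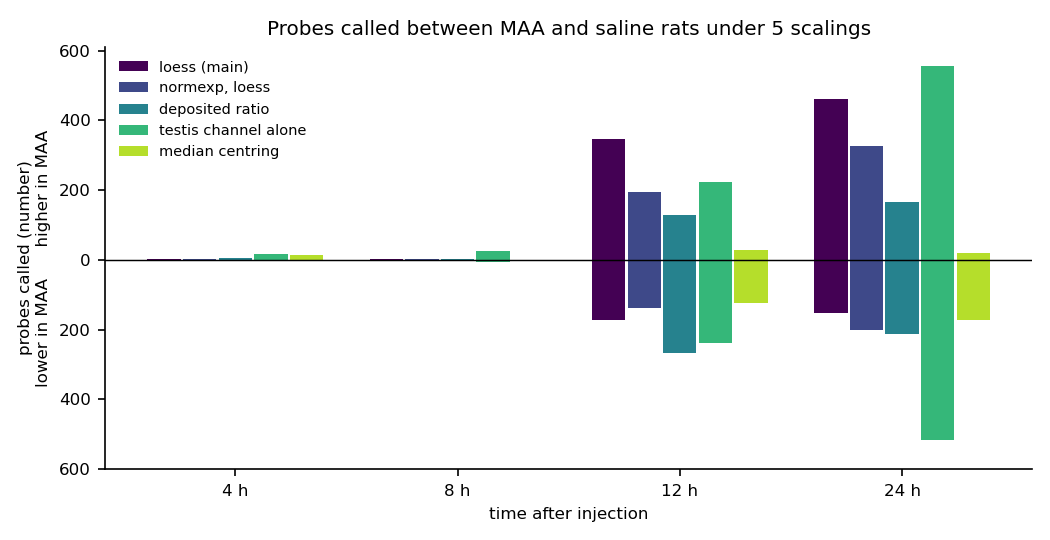
Number of probes called higher (above 0) and lower (below 0) after MAA at each time, for the loess ratio and for the other ways of scaling the arrays. At 24 h the loess ratio gives 461 higher and 151 lower, and median centring 20 higher and 173 lower.

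Among germ cell markers at 12 h, 3 of 16 spermatocyte markers fell and the other 13 did not pass. All 3 encode parts of the synaptonemal complex, which holds paired chromosomes together in meiosis: Sycp1 was 1.99-fold lower (-0.99 ± 0.17 SE, adjusted p 0.0008), Sycp2 1.58-fold lower (-0.66 ± 0.15 SE, adjusted p 0.0121, not passing without MAA_12h animal 36), and Sycp3 stood at -0.63. The list as a whole did not pass (median -0.03, camera adjusted p 0.139), with 1 higher and 4 lower adjusted over the list alone. The elongating spermatid markers rose (median 0.28, camera adjusted p 0.0012; adjusted p 0.252 with an estimated correlation), a call lost with median centring (median 0.09, adjusted p 0.304) and without saturated probes (adjusted p 0.120). Of their 17 members 2 passed, both in 0 of 5 other scalings: the linker histone gene Hils1 at 0.51 (0.24 with median centring, 0.11 with the testis channel alone) and Spata18 at 0.36 (0.12 and 0.20), and 5 passed adjusted over the list alone. Tnp2, a transition protein, was at 0.42 (adjusted p 0.124). Of 10 round spermatid markers 0 passed (median 0.11, adjusted p 0.840; 3 higher and 1 lower adjusted over the list alone), with Tcp11 at 0.41, Acrbp at 0.36 and Gopc at -0.64. Of 10 spermatogonia markers 1 rose, Uchl1 at 0.78, which fell to 0.46 and did not pass with the testis channel alone nor without MAA_12h animal 36 (list median 0.0023, adjusted p 0.558; 3 adjusted over the list alone), and Etv5 was at 0.48 (adjusted p 0.0563).

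Among somatic cell markers at 12 h, Inha, which encodes the inhibin alpha subunit of Sertoli cells, was 1.66-fold higher (0.73 ± 0.14 SE, adjusted p 0.0028), the 1 member called of 20 (median 0.16, adjusted p 0.371; 3 adjusted over the list alone). The smooth muscle genes Actg2 (0.65) and Myl9 (0.48), at 0.42 and 0.26 with median centring, rose among 8 peritubular myoid markers (median 0.16, adjusted p 0.243; 2 adjusted over the list alone). None of the 14 Leydig cell markers passed (median 0.06, adjusted p 0.791), nor any of the 18 macrophage and leukocyte markers (median 0.11, adjusted p 0.410), where RT1-Da was at 0.46. The same held for 12 endothelial markers (median -0.09, adjusted p 0.775), with Plvap at 0.45, Kdr at 0.35 and Vwf at 0.23 (-0.10 with the testis channel alone), and for 7 blood cell markers (median 0.08, adjusted p 0.866) and 5 epididymal markers (median 0.11, adjusted p 0.775). Adjusted over the list alone, 1 Leydig marker and 1 macrophage marker were higher, and 0 in the other 3 lists. S100a9 was at 0.27. Cst11 and Slc4a1 were not above background on any saline array, so no fold is given for them.

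The oxidative stress and glutathione genes rose at 12 h (median 0.20, camera adjusted p 0.0181; adjusted p 0.443 with an estimated correlation), a call lost with median centring (median 0.07, adjusted p 0.384) and with the processed channels (adjusted p 0.0854). Of 29 members 3 passed, all higher: Gstp1 (1.03), the haem oxygenase gene Hmox1 (0.92) and the peroxiredoxin gene Prdx2 (0.47, but 0.18 with median centring), and 4 adjusted over the list alone. Of 22 heat shock genes, Dnaja4 (0.61) and Hspa8 (0.55), at 0.32 and 0.33 with median centring, rose, each called in 1 of 5 other scalings (median 0.12, adjusted p 0.449; 3 adjusted over the list alone), with Hsph1 at 0.55 (adjusted p 0.0662). In the unfolded protein and integrated stress response list, Ppp1r15a rose (0.63) and the chaperone gene Dnajb9 fell (-0.77) among 23 members (median 0.16, adjusted p 0.449; 2 higher and 2 lower adjusted over the list alone). Of 35 apoptosis regulators, the somatic cytochrome c gene Cycs rose (0.50, but 0.26 with median centring) and its testis-specific counterpart Cyct fell (-0.46, and -0.77 without passing with median centring), while Bik was at 0.79 (adjusted p 0.0621). That list had a median of 0.10 and an adjusted p of 0.449, with 3 higher and 1 lower adjusted over the list alone. No p53 target gene of 17 passed (median 0.16, adjusted p 0.558; 2 adjusted over the list alone).

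Signalling and chromatin genes moved singly at 12 h. The orphan receptor gene Nr4a1 (0.76) and the MAP kinase phosphatase gene Dusp6 (0.68) rose among 24 immediate-early genes (median 0.19, adjusted p 0.139; 5 adjusted over the list alone). The NF-kappaB inhibitor gene Nfkbia (0.64, but 0.39 with median centring and 0.28 with the testis channel alone) was the 1 member called of 24 inflammatory genes (median 0.10, adjusted p 0.472) and of 19 glucocorticoid-responsive genes (median 0.14, adjusted p 0.117), with 5 members of each adjusted over the list alone. Cxcl10 was at 0.78 (adjusted p 0.0795), Socs3 at 0.60, Ddit4 at 0.53 and Fkbp5 at 0.43. The deacetylase gene Hdac1 rose (0.43, but 0.17 with median centring and called in 0 of 5 other scalings) among 18 histone acetylation and deacetylation enzymes (median 0.09, adjusted p 0.808; 3 adjusted over the list alone), with Hdac5 at 0.57 and Hdac8 at 0.55. Of 10 histone genes, H1f4 and Hils1 rose (median 0.06, adjusted p 0.875; 3 higher and 2 lower adjusted over the list alone). Of 16 genes known to rise with histone deacetylase inhibitors, 0 passed (median 0.12, adjusted p 0.433; 0 adjusted over the list alone), with Clu at 0.36.

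Metabolic and structural lists at 12 h held from 0 to 4 called members each. In the glycolysis and lactate list 4 of 26 rose, with Gpi at 0.76, Pkm at 0.50, Ldhb at 0.46 and Tpi1 at 0.40, the last 2 at 0.23 and 0.16 with median centring (list median 0.18, adjusted p 0.201; 5 adjusted over the list alone). Of 21 cell junction and blood-testis barrier genes, F11r (0.62) and Cttn (0.41), at 0.37 and 0.16 with median centring, rose (median 0.16, adjusted p 0.347; 4 adjusted over the list alone), with Ctnna1 at 0.47. Plin2 (0.42, but 0.27 with median centring), which coats lipid droplets, was called among 21 fatty acid oxidation genes and PPAR targets (median 0.12, adjusted p 0.347; 2 adjusted over the list alone), and Acads was at 0.47. The mitotic checkpoint genes Bub1b (-0.86, but -0.56 with the testis channel alone) and Cdc20 (-0.51) fell among 25 cell cycle genes (median -0.0090, adjusted p 0.347; 1 higher and 2 lower adjusted over the list alone). The calmodulin gene Calm2 fell (-0.71) and the calcium pump gene Atp2b1 rose (0.65, but 0.28 with the testis channel alone and called in 0 of 5 other scalings) among 26 calcium handling genes (median -0.0016, adjusted p 0.413; 1 each way adjusted over the list alone), with Cacna1h at -0.48. The proteasome activator gene Psme2 rose (0.73, but 0.45 with median centring and 0.27 with the testis channel alone) among 27 proteasome genes (median 0.06, adjusted p 0.808; 1 adjusted over the list alone). Nsdhl passed among 18 cholesterol synthesis genes (median 0.06, adjusted p 0.704; 3 higher and 1 lower adjusted over the list alone), from saline arrays all below background, so no fold is given. None of the 24 one-carbon and nucleotide synthesis genes passed (median 0.09, adjusted p 0.473), with Mthfd2 at 0.40, and none of 11 circadian clock genes (median 0.07, adjusted p 0.808), with Per2 at 0.47; adjusted over the list alone, 0 passed in either.

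**Figure D3:**
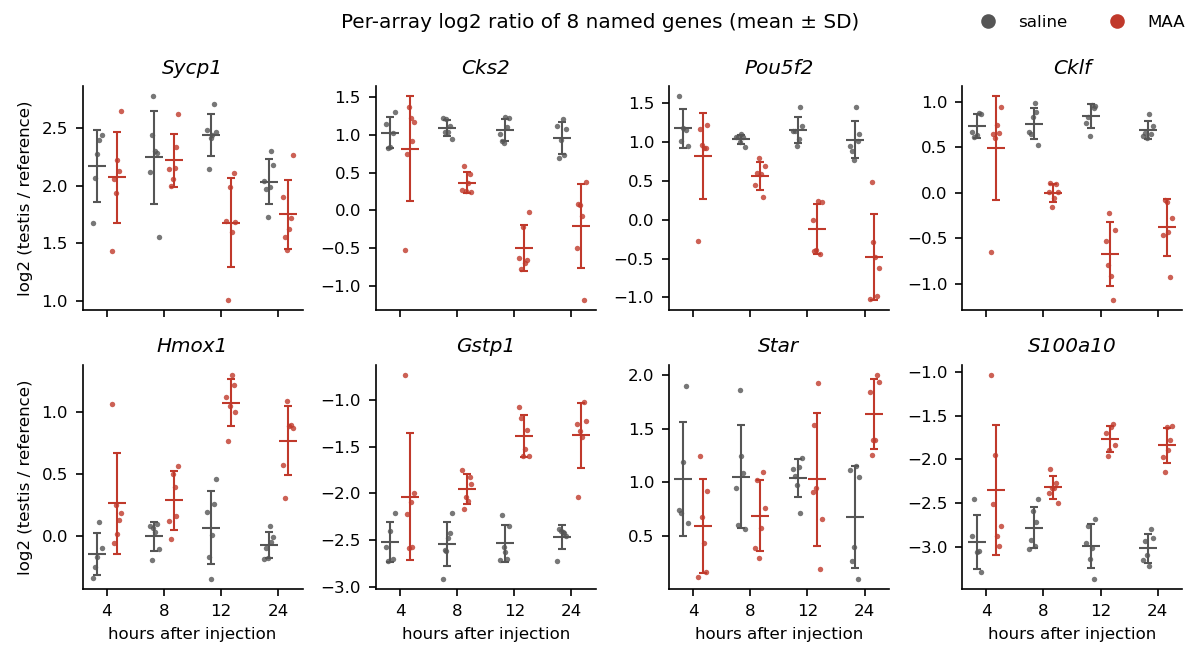
Log2 testis over reference ratio (1 unit is a doubling) of 8 named genes on each array, by treatment and time, with group mean and SD. At 12 h Cklf has a mean of 0.85 in saline and -0.68 in treated animals.

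At 24 h Gmcl1, Pou5f2, Cks2 and Cklf were again lower and a steroidogenic gene had risen, while none of the 3 synaptonemal complex genes passed. Gmcl1 was 2.93-fold lower (log2 change -1.55 ± 0.27 SE, 6 and 6 animals, adjusted p 0.00083) and Pou5f2 2.76-fold lower (-1.46 ± 0.19 SE, adjusted p 3.9e-05). Star (Gene ID 25557), which carries cholesterol into the mitochondria of Leydig cells, was 2.12-fold higher (1.09 ± 0.24 SE, adjusted p 0.0087), against -0.03 at 12 h. St3gal4 was 2.33-fold higher (1.22 ± 0.17 SE, adjusted p 0.00012) and S100a10 2.18-fold higher (1.13 ± 0.18 SE, adjusted p 0.00026).

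Mllt10, a cofactor of histone methylation, was 2.26-fold lower, Cks2 2.04-fold, and Cklf and Bbs1, a component of the ciliary BBSome, 2.03-fold each. The tetraspanin gene Cd63 was 1.96-fold higher, the transcriptional corepressor gene Ripply3 1.94-fold (0.95, but 0.37 with the testis channel alone and called in 3 of 5 other scalings) and Gstp1 1.93-fold. Star stood at 0.68 ± 0.48 (SD) in saline and at 1.64 ± 0.33 (SD) in treated animals, and its change was 1.06 and 1.40 on the 2 shared dates. Pou5f2 went from 1.03 ± 0.24 (SD) to -0.48 ± 0.55 (SD).

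With limma, 612 of 20500 probes passed at 24 h, 461 higher (75.3%) and 151 lower, for 416 genes, 328 higher and 88 lower. Of 114 called genes with several probes, 71 had all other probes on the same side. Another probe was called the same way in 10 of the 114 and the opposite way in 0. Of the 612, 238 changed at least 1.5-fold, and on the 2 shared dates, with 2 and 2 animals each, 48 and 22 passed on their own (r = 0.220 between the dates across all probes). Of the rises at 12 and 24 h, 149 probes were in both sets, against 7.78 for independent calls, and of the falls 68, against 1.27, while 0 probes passed in opposite directions. Across probes, which are not independent replicates, the log2 changes of 12 and 24 h correlated with r = 0.374, where the shared dates of the design alone give estimates a correlation of 0.073. Median centring gave 20 higher and 173 lower at 24 h and the testis channel alone 557 higher and 518 lower. Of the 461 rises 420 kept their sign in both of these, 14 also passed with median centring and 270 with the testis channel alone, and of the 151 falls 109 and 137 did. With median centring the rises of list members shrank, those of Hmox1 to 0.59, Mgst1 to 0.28, Gsta4 to 0.19, Prdx2 to 0.17, Gpx1 to 0.16, Sod1 to 0.15, Alas2 to 0.16, Tpi1 to 0.13, Cttn and Phgdh to 0.12 and Ldhb to 0.09. MAA_24h animal 44 lay at 0.364 between saline (0) and MAA (1), where the other 5 treated animals lay from 0.702 to 1.13, and 767 probes passed without it and 969 without it and MAA_4h animal 3. Without MAA_24h animal 40 the count was 305, and without saline_24h animal 45 it was 403.

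**Figure D4:**
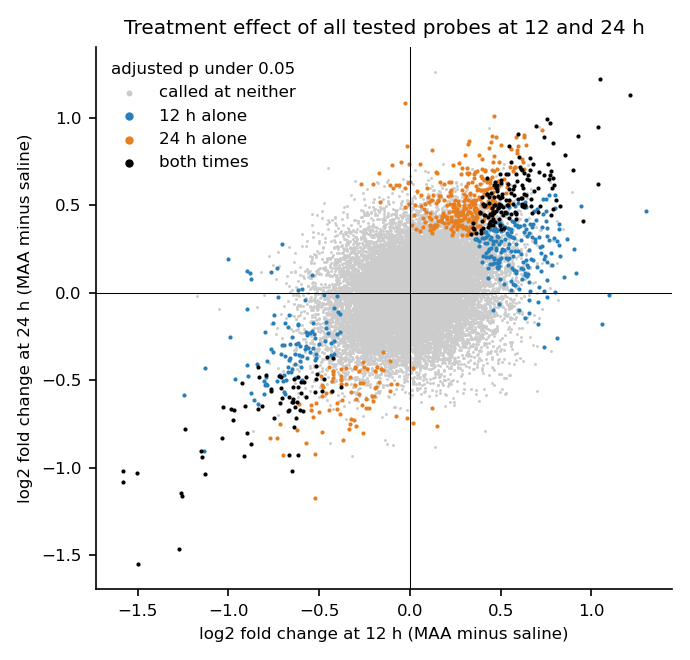
Log2 change (MAA minus saline) at 12 h against that at 24 h for each of 20500 probes, coloured where called at 12 h, at 24 h or at both. Of the 346 rises at 12 h, 333 are above 0 at 24 h, and of the 172 falls 162 are below 0.

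The oxidative stress and glutathione genes had the most called members of any list at 24 h. Of 29 members 8 rose and 0 fell, and 12 rose adjusted over the list alone (median 0.29, camera adjusted p 9.2e-05; adjusted p 0.0966 with an estimated correlation). Hmox1 was 1.86-fold higher (0.90 ± 0.13 SE, 6 and 6 animals, adjusted p 0.00017) and Prdx2 1.51-fold (0.60 ± 0.12 SE, adjusted p 0.0032). Gstp1 (0.95), Mgst1 (0.68), the cystine transporter gene Slc7a11 (0.63), Sod1 (0.51), Gpx1 (0.49) and Gsta4 (0.47) also rose. With median centring, which uses no loess, the list median was 0.02 and did not pass (adjusted p 0.304), and with the testis channel alone it was 0.27 (adjusted p 5.2e-05).

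Among somatic cell markers at 24 h, Star rose, and so did Hsd11b1 (0.43, but 0.05 with median centring, called in 0 of 5 other scalings and in 31 of 47 fits without 1 array), among 14 Leydig cell markers (median 0.14, adjusted p 0.413; 3 higher and 1 lower adjusted over the list alone). Cyp2a1 was not above background on any array of either group, so no fold is given. The protease gene Ctsl (0.90) and Aard (0.60), at 0.57 and 0.32 with median centring, rose among 20 Sertoli cell markers (median 0.12, adjusted p 0.285; 3 adjusted over the list alone). Myl9 was 1.49-fold higher (0.58, but 0.24 with median centring) among 8 peritubular myoid markers (median 0.06, adjusted p 0.433; 1 adjusted over the list alone), with Lmod1 at 0.51 (adjusted p 0.397), or 0.05 without MAA_24h animal 47. Alas2, of haem synthesis in red cells, rose (0.50) among 7 blood cell markers (median 0.03, adjusted p 0.875; 1 adjusted over the list alone). None passed, over all genes or adjusted over the list alone, among 18 macrophage and leukocyte markers (median 0.11, adjusted p 0.473), with Cd163 at 0.59 and Lyz2 at 0.52 (-0.14 with the testis channel alone), among 12 endothelial markers (median 0.12, adjusted p 0.803) and among 5 epididymal markers (median -0.0093, adjusted p 0.843), with Spink8 at 0.28 (-0.12 with median centring).

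Among germ cell markers at 24 h, the meiotic mismatch repair gene Mlh3 fell (-0.68) and the cohesin gene Smc1b rose (0.45, but 0.18 with median centring) among 16 spermatocyte markers (median -0.05, adjusted p 0.347; 1 higher and 2 lower adjusted over the list alone). Sycp1 was at -0.25 (adjusted p 0.52) and Sycp2 at -0.45 (adjusted p 0.0712). The elongating spermatid markers rose as a list (median 0.28, camera adjusted p 0.0076; adjusted p 0.390 with an estimated correlation), though 0 of 17 passed singly and 7 did adjusted over the list alone. The call was lost with median centring, where the median turned to -0.05, and with the testis channel alone (0.04, adjusted p 0.370). It was also lost with normexp (adjusted p 0.225), the deposited ratio (adjusted p 0.251) and the processed channels (adjusted p 0.230). Without saturated probes it did not pass either (adjusted p 0.507). Id4, a marker of spermatogonial stem cells, was 1.68-fold higher (0.75 ± 0.17 SE, adjusted p 0.0117; 0.38 with median centring, called in 2 of 5 other scalings and not without MAA_24h animal 47), the 1 member called of 10 spermatogonia markers (median 0.16, adjusted p 0.433; 1 adjusted over the list alone). Of 10 round spermatid markers 0 passed (median 0.05, mean 0.0025, with a camera statistic on the lower side, adjusted p 0.903; 0 adjusted over the list alone).

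The cell cycle genes were lower at 24 h (median -0.09, camera adjusted p 0.0181, or 0.0966 with an estimated correlation). The call was lost without saline_24h animal 41, where 3 lists passed, 3 higher and 0 lower. Cdc20 fell (-0.46), the 1 member called of 25, and 3 fell adjusted over the list alone, with Cdk1 at -0.49 (adjusted p 0.0672). Of 10 histone genes, H2ax, whose product marks DNA breaks, was lower (-0.59 ± 0.15 SE, adjusted p 0.0205, and -0.94 with median centring; list median -0.03, adjusted p 0.473; 1 higher and 2 lower adjusted over the list alone). None of 18 histone acetylation and deacetylation enzymes passed (median 0.05, adjusted p 0.960; 0 adjusted over the list alone), and none of 16 genes known to rise with histone deacetylase inhibitors (median 0.12, adjusted p 0.433; 1 adjusted over the list alone), with Vamp2 at 0.55 and Klf4 at 0.39.

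Stress lists other than the oxidative one did not pass at 24 h. Ccng1 rose (0.44, but 0.19 with median centring and called in 1 of 5 other scalings) among 17 p53 target genes (median 0.18, adjusted p 0.313; 2 adjusted over the list alone), with Bax at 0.53 (adjusted p 0.0785). Cycs was 1.56-fold higher (0.64, but 0.29 with median centring) among 35 apoptosis regulators (median 0.09, adjusted p 0.739; 1 adjusted over the list alone). Dnaja4 (0.54, but 0.11 with median centring and 0.08 with the testis channel alone) rose among 22 heat shock genes (median 0.04, adjusted p 0.791; 6 higher and 1 lower adjusted over the list alone). Slc7a11 and the serine synthesis gene Phgdh (0.45) rose among 23 unfolded protein and integrated stress response genes (median 0.05, adjusted p 0.470; 3 adjusted over the list alone). Nr4a1 (0.65) was called among 24 immediate-early genes (median 0.15, adjusted p 0.266; 4 adjusted over the list alone). None passed among 19 glucocorticoid-responsive genes (median 0.07, adjusted p 0.634) and 24 inflammatory genes (median 0.01, adjusted p 0.908), nor adjusted over either list alone.

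Of 26 glycolysis and lactate genes at 24 h, Tpi1 (0.51), the lactate transporter gene Slc16a7 (0.51, but 0.19 with median centring) and Ldhb (0.46) rose and Pfkp (-0.45) fell (median 0.17, adjusted p 0.0807; 7 higher and 1 lower adjusted over the list alone). F11r was 1.62-fold (0.70, but 0.29 with median centring) and Cttn 1.41-fold higher among 21 cell junction and blood-testis barrier genes (median 0.07, adjusted p 0.313; 2 adjusted over the list alone). Cpt2, of fatty acid import into mitochondria, fell (-0.44, and -0.70 with the testis channel alone) among 21 fatty acid oxidation genes and PPAR targets (median 0.05, adjusted p 0.803; 1 each way adjusted over the list alone). Hprt1 (0.48, but 0.14 with median centring) and Phgdh rose among 24 one-carbon and nucleotide synthesis genes (median -0.0031, mean 0.01, adjusted p 0.903; 2 adjusted over the list alone). Fdps (0.46, but 0.06 with median centring) rose among 18 cholesterol synthesis genes (median 0.06, adjusted p 0.685; 3 adjusted over the list alone), with Cyp51 at 0.33 (-0.02 with median centring), and Psma5 (0.39, but 0.02 with median centring and called in 1 of 5 other scalings) among 27 proteasome genes (median 0.11, adjusted p 0.148; 4 adjusted over the list alone), with Psma1 at 0.37. None of 26 calcium handling genes passed (median -0.0022, mean 0.0028, adjusted p 0.511) and none of 11 circadian clock genes (median 0.11, adjusted p 0.739), with Per3 at 0.17; adjusted over the list alone, 0 passed in either.

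**Figure D5:**
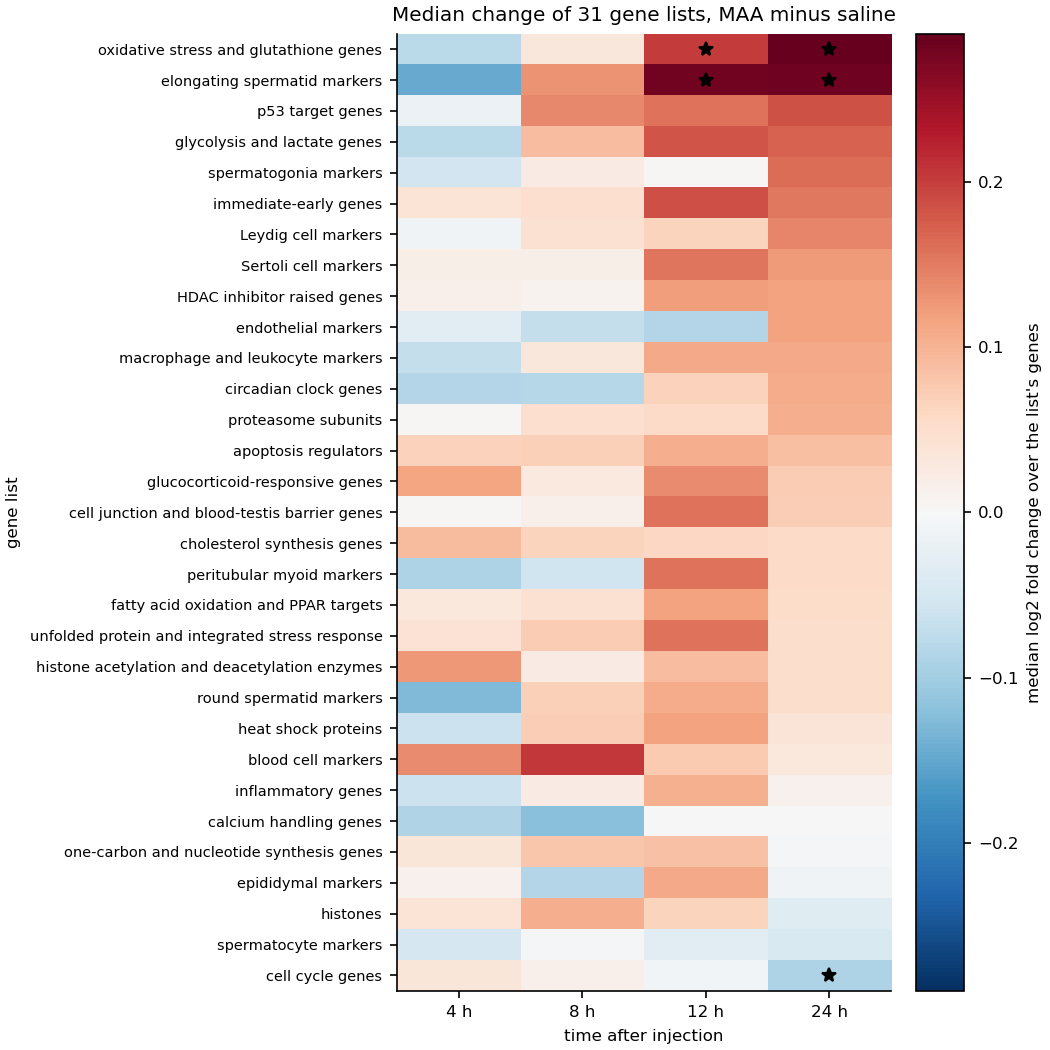
Median log2 change (MAA minus saline) of the measured members of each of the 31 gene lists at 4, 8, 12 and 24 h, as colour. The oxidative stress and glutathione genes go from -0.08 at 4 h to 0.03, 0.20 and 0.29, and lists that passed camera are marked.

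The effect of MAA was then compared between times, to ask which transcripts respond late rather than only pass late. Cd63 changed by -0.12 and 0.14 at 4 and 8 h and by 0.77 and 0.97 at 12 and 24 h (adjusted p of the difference 0.0266, 6 animals a group but 5 for saline at 4 h). Bbs1 went from 0.21 at 4 h to -0.34, -0.65 and -1.02 (adjusted p 0.0266), and Prdx4, a peroxiredoxin of the endoplasmic reticulum, from -0.25 to 0.16, 0.60 (0.36 with median centring) and 0.54 (adjusted p 0.0266). Lsr, a lipoprotein receptor of epithelial junctions, stood at 0.06 and 0.0026 before and at 0.79 and 0.66 after (adjusted p 0.0296). Maoa stood at 0.23, 0.02, 0.95 and 0.41 (adjusted p 0.0402).

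With limma's F test over the 4 times, 26 of 20500 probes passed, 18 of them with 1 gene symbol, and 2271 had an unadjusted p under 0.05. Of the 26, 11 were called higher and 14 lower at 12 or 24 h, and 0 were called at 4 or 8 h. Between single times, 44 probes differed between 12 and 4 h (21 more positive, 23 more negative later), 66 between 24 and 4 h (48 and 18), 1 between 12 and 8 h and 0 in the other 3 pairs, which had 1291 (8 against 4 h), 1655 (24 against 8 h) and 1314 (24 against 12 h) at an unadjusted p under 0.05. Without MAA_24h animal 44 the F test passed 82 probes, without MAA_4h animal 3 it passed 73, and without both 216. It passed 0 without any 1 of MAA_24h animal 39, MAA_4h animal 4, saline_4h animals 2 and 10, saline_12h animal 30 and saline_24h animal 41, and the count moved over 1.5 times for 39 of the 47 arrays.

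The saline animals of the 4 times give the background change between times without treatment. Ndufc1, of mitochondrial complex I, had the smallest p of any named gene and stood at -0.83, -0.49, -0.74 and -0.43 at 4, 8, 12 and 24 h (SD 0.22, 0.52, 0.29 and 0.31, adjusted p 0.185). Camk1g, Begain, Rab4a and the replication gene Mcm3 followed, each with an adjusted p of 0.475. With limma's F test 1 of 20500 probes passed, and 1499 had an unadjusted p under 0.05. That probe (probe_21259) has no gene symbol here and had means of 0.62, 0.21, 0.01 and -0.24 (adjusted p 0.0475).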

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

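The tests on MAA_4h animal 3 and on an exchange of animals 3 and 44 were chosen after the positions were seen, and so was the position itself. A sample is listed here when its gap to the nearest of its group exceeds Dixon's 95% limit as a share of the group's range. This held in 24 of 246 groups, against 12.3 by chance.

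MAA_24h animal 44 accounts for 9 of the 24. It was the lowest of the 6 treated animals for Cd63 (0.628), Gstp1 (0.628), the Sertoli genes Ctsl (0.763) and Aard (0.701), Cycs (0.651), Myl9 (0.647), Hprt1 (0.708) and Spink8 (0.629), and highest for the cell cycle gene Cdk1 (0.838). MAA_4h animal 3 was far above its group in position between saline and MAA, with shares of 0.951 on the 12 h axis and 0.784 on the 24 h axis. It lay apart in 10 of 112 named probes, against 5.6 by chance.

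Animal 3 lay at 0.913 on the 12 h axis, where the other 5 treated 4 h animals lay from 0.203 to 0.238 and the treated 12 h animals from 0.750 to 0.971, so its testis looked like that of a later time, and a wrong time label may explain it. The lowest treated animals of 8, 12 and 24 h lay at 0.391, 0.750 and 0.538 on that axis, all above the other 4 h animals. This argues against an exchange of labels with 1 of these later animals. Animal 44 lay at 0.364 on the 24 h axis, above all saline 24 h animals (0.0473 to 0.204), which argues against a saline label, and at 0.538 on the 12 h axis, above the other 4 h animals, which argues against an exchange with animal 3. The hybridisation dates are argued against by their other treated arrays, an 8 h animal at 0.438 and a 12 h animal at 0.875, each inside the range of its own group. With the testis channel alone animals 3 and 44 lay at 0.97 and 0.376. A faster or slower response of these animals to MAA stays open and was not tested.

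The other outliers at 12 h after MAA were animal 36 for Hspa8 (0.768), Gopc (0.714) and Dnajb9 (0.686), animal 35 for Ctnna1 (0.704), animal 31 for Acads (0.719), and animal 27 for Tnp2 (0.630) and Kdr (0.726). At 24 h they were treated animal 39 for Lyz2 (0.646) and Per3 (0.670) and treated animal 47 for Lmod1 (0.793). Among saline 24 h animals they were 38 for St3gal4 (0.634) and 37 for Gstp1 (0.770) and Bbs1 (0.71).

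For 12 named genes the effect of MAA itself differed between times by limma's F test. The adjusted p was 0.0266 for Bbs1, Cd63 and Prdx4, 0.0296 for Lsr, 0.0402 for Cklf, Maoa and St3gal4, 0.0469 for Gmcl1, Pou5f2, Ripply3 and Thoc7, and 0.0483 for the glycolytic gene Gpi, which stood at 0.76 at 12 h and 0.18 at 24 h.

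The channel of the reference RNA, which should not respond to treatment, gave 2 called probes at 4 h and 0 at the other times. They are probe_1054 (0.87) and probe_1841 (0.69), without a gene symbol here, both with an adjusted p of 0.0266, and they are not among the probes called at 4 h.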

How the results depend on the processing

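Chosen after the data were seen were normexp, the testis channel alone, the deposited ratio and processed channels, leaving out spots with image flag 3, saturated probes or animals 3 and 44, while the other settings were planned. Main counts were 4, 2, 518 and 612 probes at 4, 8, 12 and 24 h, 26 for the difference between times, 1 for the saline times and 5 lists. None of the 75 named calls turned sign in any setting but the Cy5 channel alone and the series table as labelled, where 28 and 26 kept it, and 44 of the 75 passed in every fit without 1 array. Of the 75, 68 still passed without the date term, 34 with median centring, 56 with the testis channel alone, 56 with the deposited ratio, 63 with normexp, 46 at an adjusted p under 0.01 and 75 without animals 3 and 44. In the 5 other scalings 8 of the 75 passed in 0: Nsdhl, Atp2b1, Hils1, Hdac1 and Spata18 at 12 h and Hprt1, Fdps and Hsd11b1 at 24 h. In fits without 1 array, Atp2b1 passed in 18 of 47, Spata18 in 19, Nsdhl in 23, Hsd11b1 in 31, Dusp6 in 34, Cdc20 in 36, Ccng1 in 37, Cyct, Hdac1 and Hprt1 in 38, Psma5, Slc7a11 and H2ax in 41, Hils1 and Dpf1 (4 h) in 42, and Hspa8, Plin2 and Mlh3 in 43. Signal over background limits Fstl1, Nsdhl, Cst11, Slc4a1 and Cyp2a1. Unless said otherwise the cause of a change was not tested.

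Scaling moved the counts. Median centring gave 14, 1, 153 (28 higher, 125 lower) and 193 (20 and 173) probes at 4, 8, 12 and 24 h, 139 for the difference between times, 0 for the saline times and 3 lists, 0 higher and 3 lower, where the main lists were 4 higher and 1 lower. The testis channel alone gave 17, 32, 461 and 1075 probes, then 50 and 0, and 6 lists, 3 higher and 3 lower. The deposited ratio gave 5 at 8 h, 394 at 12 h (128 higher, 266 lower) and 378 at 24 h (165 and 213), and the processed channels 7, 6, 362 (129 and 233) and 354 (152 and 202) at the 4 times and 3 lists, with 0 for the saline times in both. Normexp gave 4 at 8 h, 333 at 12 h, 10 for the difference between times and 0 for the saline times. The channel headed Cy5, the reference here, gave 2, 0, 0 and 0 probes and 0 for the difference between times, and the series table as labelled 0 in each comparison; its columns belong largely to other arrays. Quantile scaling of the mean intensities after loess leaves M as it is (largest change 0), and omitting background correction is the main setting, so neither gave a new value.

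The model and the thresholds mattered for short lists of probes. Without the date term 13 probes passed at 8 h, 10 differed between times and 0 between saline times. With date as a random term (correlation 0.069) 10 passed at 4 h, 18 at 8 h and 0 between saline times. Array weights gave 5 at 8 h, 43 for the difference between times and 0 for saline, and the trended robust fit 66 and 0 for the last 2. The detection filter gave 4 at 8 h, and genes in place of probes 1. An adjusted p under 0.01 left 157 and 190 at 12 and 24 h and 0 in both F tests, and a 1.5-fold minimum 274 and 238, as stricter limits must lower a count. Fits of 2 groups alone, without the date term and with fewer arrays for the spread, gave 0, 7 and 117 at 4, 8 and 24 h. Single dates, with 2 animals a group but 1 treated one on the second date of 12 h, gave 0 and 0, 1 and 0, 18 and 6, and 48 and 22 at the 4 times. Leaving out spots with image flag 3 gave 7 at 4 h and 3 for the difference between times, and leaving out saturated probes 3 lists. With an estimated correlation 0 lists passed.

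Leaving out animals 3 and 44 gave 9 at 8 h, 969 at 24 h, 216 for the difference between times and 0 for the saline times. Leaving out 1 array gave from 3 to 6 probes at 4 h, 2 to 9 at 8 h (9 without MAA_4h animal 3), 226 (MAA_12h animal 36) to 614 (MAA_4h animal 3) at 12 h and 305 (MAA_24h animal 40) to 777 (MAA_4h animal 3) at 24 h. It gave 0 (any 1 of MAA_24h animal 39, MAA_4h animal 4, saline_4h animals 2 and 10, saline_12h animal 30 and saline_24h animal 41) to 82 (MAA_24h animal 44) for the difference between times, 0 (saline_12h animal 25) to 2 (MAA_8h animal 23) for the saline times, and 3 (saline_24h animal 41) to 7 (MAA_4h animal 7) lists. The count moved over 1.5 times for 9 arrays at 8 h, 6 at 12 h, 2 at 24 h, 39 for the difference between times and 36 for the saline times.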

Other observations

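Tests chosen after their results were seen are those of spermatocyte share and hybridisation date for the falls at 12 h and that of loess for the oxidative stress genes. The genes of the next paragraph were named after their values were seen.

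Besides the genes already given, the effect of MAA differed between times for the actin-severing gene Dstn, at -0.02 and 0.15 at 4 and 8 h and 0.68 and 0.74 at 12 and 24 h (adjusted p 0.0402), and for the sialyltransferase gene St6galnac2, at 0.45 and 0.57 at 12 and 24 h (adjusted p 0.0432). Slbp, which binds the stem-loop of histone mRNA, stood at 0.22, -0.34, -0.92 and -0.51 (adjusted p 0.0432). Cox19, of cytochrome oxidase assembly, was at -0.65 and -0.62 at 12 and 24 h (adjusted p 0.0402) and Efcab14 at -0.57 and -0.60 (adjusted p 0.0402), while Fam209 rose at 24 h alone among the calls (0.56, adjusted p of the difference 0.0493).

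Calls among genes that the testis holds less of than the reference RNA were mostly higher, though most of these genes did not pass. Of the 965 genes with the lowest testis over reference ratio, 87 rose and 2 fell at 12 h and 93 rose and 3 fell at 24 h. Of the 965 with the highest ratio 56 rose and 31 fell at 12 h and 102 rose and 36 fell at 24 h. The medians of these low and high genes were 0.16 and 0.08 at 12 h (0.02 and -0.06 with median centring, 0.09 and 0.04 with the testis channel alone) and 0.10 and 0.10 at 24 h (-0.11 and -0.11, and 0.10 and -0.0026). By fry, which asks if a list's genes move one way on balance and compares them with no other genes, 0, 0, 16 and 13 of 31 lists passed at 4, 8, 12 and 24 h. By its mixed test, for changes either way, the unfolded protein and integrated stress response genes (adjusted p 0.0191) and the cell junction genes (adjusted p 0.0432) passed at 4 h and the one-carbon and nucleotide synthesis genes (adjusted p 0.0456) at 8 h. The elongating spermatid marker median of 12 h (0.28) lay at the 99.3 percentile of lists matched on intensity, whose median was 0.11, and 13 of the 17 genes are among the brightest 5% and 9 were saturated on some array.

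The 172 falls at 12 h had a median of -0.66. The 16 spermatocyte markers had a median of -0.0321 (SE 0.13), and 1 of them fell that far. As a set the markers did not fall by that amount. The falls were selected for their size, however, and Sycp1, Sycp2 and Sycp3 were called lower. A smaller loss of spermatocytes, or a loss limited to some of their stages, is therefore not excluded. The 24 h arrays share 4 dates with those of 12 h, so hybridisation date was tested on the 2 dates that hold both 24 h groups and no 12 h array. It is argued against by the 93.0% of the falls at 12 h that were lower on each of them, against 47.1% and 45.6% of all probes. With both median centring and the testis channel alone 99.4% of the falls were lower. Keeping the sign decides little on loess, as 342 of the 346 rises did so too. Of the falls, 113 also passed with median centring and 125 with the testis channel alone. Neither uses loess, which argues against it for those falls. A candidate explanation is that MAA lowers these transcripts, among them Cks2, Sycp1 and Pou5f2, within cells that are still present. This is a hypothesis found on these same data, and RNA of isolated spermatocytes at 12 h, not analysed here, would decide it.

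For the rise of the oxidative stress and glutathione genes at 24 h, loess and a higher share of somatic cells remain open. The list did not pass with an estimated correlation (adjusted p 0.0966) or with median centring (adjusted p 0.304) and passed with the testis channel alone (adjusted p 5.2e-05), so loess and a response to MAA cannot be told apart by these scalings. Among random lists matched on testis over reference ratio and intensity the list median lay at the 99.99 percentile, against a matched median of 0.10. Such lists take the members as uncorrelated. The ratio sets the testis against the reference RNA, not somatic against germ cells. The lists therefore cannot decide on a higher share of somatic cells. Between animals of the same hybridisation date the list median was above 0 too, at 0.169 and 0.336 on the 2 shared dates. The main fit already holds a term for date and uses these same arrays, so positive medians there were nearly set by the main result. They are therefore no separate test of hybridisation date, which was not tested on other arrays for this list. A response of the treated testis to MAA is an explanation that the design offers. It may account for the rise only as far as the scaling and the share of somatic cells allow.

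Other splits of the same arrays into groups of the same sizes, 100 for each result with the real one, were counted. For the probes called at 12 h and 24 h, 1 split of 100 gave as many, the real one (518 and 612, highest other 14 and 3). This argues against chance for these 2 counts. For the difference between times 1 split gave as many too, the real one (26 probes, highest other 1). That count was 0 without any 1 of 6 arrays and 0 at an adjusted p under 0.01. Its other splits moved time labels across dates and mixed early with late animals, which can lower their counts. Chance is therefore not excluded for the difference between times. For the 2 probes at 8 h 4 splits gave as many (highest other 2), and for the 4 lists at 24 h, adjusted over the 31 lists of that time, 3 splits did (highest other 5). These shares lie just under the limit of 0.05 without adjustment over the results tested, and other splits reached the same or more. Chance is therefore not excluded for them. Chance is not excluded for the 4 probes at 4 h (6 splits, highest other 16), the 2 lists at 12 h (10 splits, highest other 4) or the 1 probe of the saline times (8 splits, highest other 2).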
